A study of Mus musculus with 8 samples.

How the data were processed

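RNA of follicular B cells was measured on 8 single-colour short-oligonucleotide arrays, in 4 groups of 2: IgM unstimulated, IgM with HEL, IgMG unstimulated and IgMG with HEL. Groups and replicate numbers were taken from the sample titles, and the number of mice (2 to 8) and sorts (1 to 3) pooled per array from the labels. The titles number the replicates as experiments. The counts do not show whether any arrays shared mice or sorts.

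The authors deposited 1 intensity per probe set and array, on a linear scale, calculated with MAS 5 per the submitters' processing notes. The deposited intensities of each array had a mean close to 150.0 after trimming 2% at each end, which is how the scaling was recognised from the values; other settings are not given in the sources used here. Such scaling assumes a like total signal on every array, and summaries of dim probe sets are noisy. Detection calls were not used here.

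From the 12488 probe sets, 66 control probe sets were left out of the tests. Signals were analysed as log2(signal + 16), which understates the change of dim genes. The brightest 60% by mean over all 8 arrays, 7453 of 12422, were tested. Their lowest mean signal was 22.9. Gene symbols came from the platform's annotation of 2016, in which 10833 probe sets had 1 symbol, 396 several and 1193 none, and probe sets with several symbols were not named. Updating by gene identifier against the GRCm38.p6 gene table matched 10839 of 10855 and changed 0 symbols. A gene with several probe sets is given by the brightest.

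Tests were two-sided and used limma 3.58.1 in R 4.3.3, with a coefficient per group over all 8 arrays, eBayes with a trend, and Benjamini-Hochberg adjustment at 0.05. The contrasts were both HEL responses, their difference, IgMG against IgM without and with HEL, the mean HEL response and the mean IgMG effect. With 2 arrays per group, 4 residual degrees of freedom were joined by 4.87 prior ones. Errors beside log2 changes are standard errors of the fit, and those beside signals are SDs of 2 arrays.

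Of 32 gene lists fixed before the data were examined, 30 had at least 5 tested genes; the lists of B-1 cell and platelet markers did not. They were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, with an estimated correlation and fry beside it. Genes were named by a rule fixed at the same time: the 10 largest rises and falls past the threshold without overlap of the groups, the 10 smallest p where fewer than 10 passed, up to 5 members of each described list, and the always-named genes Ighm, Ighg1, Cd79a, Cd79b, Cd22, Egr1, Egr2, Myc, Cd69, Cd86, Nr4a1, Nfkbia, Ccnd2 and Bcl2l1. Ighg1 and Cd69 had no probe set with 1 symbol. In IgM cells Ccnd2 and Bcl2l1 had log2 changes with HEL of -0.79 ± 0.40 and -0.65 ± 0.27, and Cd79a, Cd79b and Cd22 of 0.18 ± 0.17, -1.01 ± 0.14 and -0.98 ± 0.15, of which those of Cd79b and Cd22 passed the threshold.

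The scripts were tested on simulated data with 200 of 7453 probe sets changed. A log2 change of 1 was recovered in 44% of probe sets for the response in IgM cells and 40.5% in IgMG cells, and a change of 2 in 97.5% for each. Variations of the processing listed before the data were examined covered the offset, the scaling, the filter, the trend, the arrays in the fit, a replicate block, each array left out, averaging of probe sets, the threshold, a rule without a test, the choice of responding probe sets and the list test. Alternatives chosen after seeing the data were the Gapdh 5'/3' ratio as a covariate, leaving out both arrays that stand apart, a crossed pairing, and a response size on probe sets chosen once on all 8 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.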

Results

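Follicular B cells of mice were profiled with 8 single-colour oligonucleotide arrays. The cells carried an antigen receptor specific for hen egg lysozyme (HEL), either as an IgM or as a chimera called IgMG, in which the spacer outside the cell, the membrane-spanning part and the cytoplasmic part of IgM were exchanged for those of IgG1. Cells of each kind were left unstimulated or were stimulated with HEL, which gave 4 groups of 2 arrays. Each array pooled sorted cells from 2 to 8 mice, collected in 1 to 3 sorts. The IgM arrays pooled 2 or 4 mice and the IgMG arrays 5 to 8. Receptor and number of mice pooled therefore cannot be told apart in any comparison of the receptors. The length of the stimulation is not given in the sources used here. Median signal per array lay between 40.5 and 47.7, and 7453 of 12422 probe sets were bright enough to be tested. The number of arrays limits the precision: an exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so the adjusted p-values of the comparisons come from limma, which shares its estimate of the spread across probe sets.

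Before the comparisons, the receptor transcripts were looked up. Ighm, the IgM heavy chain, had a mean signal of 10594 ± 133 (SD, n = 2) in unstimulated IgM cells and 10645 ± 2600 (SD, n = 2) in unstimulated IgMG cells, a log2 difference of -0.01 ± 0.18 (SE). It changed by 0.23 ± 0.18 (SE) in IgM cells with HEL, with an adjusted p = 0.451 from limma, and its other probe set had the opposite sign. The position of the Ighm probes relative to the exchanged part is not known here, so Ighm checks nothing about the chimera. Cd79a, a signalling partner of the receptor, had a log2 difference of 0.05 ± 0.17 (SE) between unstimulated IgMG and IgM cells, and Cd79b, its dimer partner, of -0.06 ± 0.14 (SE).

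The first comparison asked which genes antigen changed in IgM B cells. HEL raised the transcription factor genes Egr2, Nr4a1 and Egr1 of the immediate-early class and the chemokine genes Ccl4 and Ccl3. Egr2 went from a signal of 29.9 ± 11.8 to 3688 ± 6.58 (SD, n = 2 each), a log2 change of 6.36 ± 0.24 (SE), and Nr4a1 rose by 5.57 ± 0.35. Ccl4 rose by 5.94 ± 0.28 and Ccl3 by 4.36 ± 0.32 on the log2 scale. Klf2, a transcription factor of resting lymphocytes, fell from 1009 ± 88.4 to 53.1 ± 43.6 (SD, n = 2 each), a log2 change of -4.05 ± 0.38 (SE). By limma, 499 probe sets rose and 542 fell at an adjusted p under 0.05, and 293 and 282 of these changed at least 2-fold.

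Among the largest rises in IgM cells were also Bhlhe40 (log2 change 5.35 ± 0.27), Gfi1 (5.25 ± 0.36), the kinase gene Plk2 (5.02 ± 0.21), Egr1 (4.65 ± 0.28), the Egr partner Nab2 (4.63 ± 0.20) and Irs2 (3.75 ± 0.24). Across the processing variations Bhlhe40 ranged from 4.07 to 6.26, Gfi1 from 3.79 to 6.53 and Egr1 from 2.42 to 5.04. Among the largest falls were the fatty acid desaturase Scd2 (-3.18 ± 0.25), Gbp3 (-2.83 ± 0.40), Rabgap1l (-2.82 ± 0.29), Trim59 (-2.65 ± 0.32), the cytokine receptor Il10ra (-2.48 ± 0.33), Id3 (-2.43 ± 0.22) and Il16 (-2.30 ± 0.22). Their adjusted p-values in limma reached at most 0.00277, for Gbp3.

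Of 15 tested immediate-early transcription factors, 11 rose and 0 fell in IgM cells (11 and 0 adjusted over the list alone), and Myc rose by 3.69 ± 0.22. Of 28 ribosome biogenesis genes 19 rose (25 adjusted over the list alone), with Gnl3 at 2.94 ± 0.21, Tsr1 at 1.82 ± 0.19 and Nhp2 at 1.73 ± 0.16. Of 19 heat shock and chaperone genes 8 rose (12 adjusted over the list alone), with Hsph1 at 1.94 ± 0.22, Dnaja1 at 1.64 ± 0.19 and Hspa8 at 1.27 ± 0.22. Of 19 genes of the NF-kB pathway and its targets, 10 rose and 3 fell (11 and 3 adjusted over the list alone). Cd83 rose by 3.69 ± 0.28, Tnf by 1.92 ± 0.23, Relb by 1.46 ± 0.22 and the inhibitor gene Nfkbia by 0.83 ± 0.16, while the lymphotoxin gene Ltb had a log2 change of -1.10 ± 0.15. A second Relb probe set went the other way and a second Nfkbia probe set differed in call. These 4 lists had camera adjusted p-values of 2.12e-12, 1.14e-13, 3.22e-08 and 3.01e-04 in limma, but with an estimated correlation the adjusted p = 0.143 for each.

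Of 8 MAPK feedback genes, 4 rose and 1 fell in IgM cells (4 and 1 adjusted over the list alone). Gem rose by 2.90 ± 0.21 and Dusp2 by 2.56 ± 0.22, while Dusp6, a phosphatase of ERK kinases, had a log2 change of -1.90 ± 0.18. Of 10 surface molecules of B cell activation, 5 rose and 1 fell (6 and 2 adjusted over the list alone), with the costimulatory Cd86 at 2.50 ± 0.41, Plaur at 2.08 ± 0.28 and Cd5 at 1.64 ± 0.29. Of 17 plasma cell and unfolded protein response genes 6 rose (6 adjusted over the list alone). Irf4 rose by 3.72 ± 0.17, Ddit3 by 2.56 ± 0.20, Atf4 by 1.59 ± 0.18 and the chaperone Hspa5 by 1.42 ± 0.21. Of 16 translation factors 7 rose and 1 fell, of 17 genes of amino acid transport and one-carbon metabolism 4 rose, and Shmt1 of the latter rose by 2.71 ± 0.24.

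Falls in IgM cells gathered in 2 lists. Of 16 quiescence and recirculation genes 8 fell and 2 rose (12 and 2 adjusted over the list alone), with Klf2 as above, Sesn1 at -2.25 ± 0.31 and Klf3 at -1.29 ± 0.24, while the chemokine receptor Ccr7 rose by 1.92 ± 0.27. Of 22 interferon-stimulated genes 11 fell and 0 rose (13 and 0 adjusted over the list alone), with Ifit3 at -1.96 ± 0.30 and Mx1 at -1.68 ± 0.28. Camera in limma gave adjusted p = 0.00157 and adjusted p = 3.75e-05 for these lists, but with an estimated correlation the adjusted p = 0.143 for each.

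In all, camera placed 14 of 30 lists past the threshold in IgM cells, 12 higher and 2 lower, and limma's fry placed 14. With an estimated correlation 0 of 30 lists passed, and the lowest adjusted p = 0.143. Markers of NK, myeloid and erythroid cells were not past the camera threshold in IgM cells (adjusted p = 0.984, 0.984 and 0.593), and neither were those of T cells or of follicular and transitional B cells (adjusted p = 0.605 and 0.571), or of marginal zone B cells (median 0.04). The second HEL-stimulated IgM array had the highest Gapdh 5'/3' signal ratio, 0.755 against 0.140 to 0.395 on the other arrays, and the lowest myeloid and erythroid marker levels. The 1041 calls became 359 without that array, 340 without the first and 500 without the second unstimulated IgM array, and 603 with the 5'/3' ratio as a covariate.

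**Figure D1:**
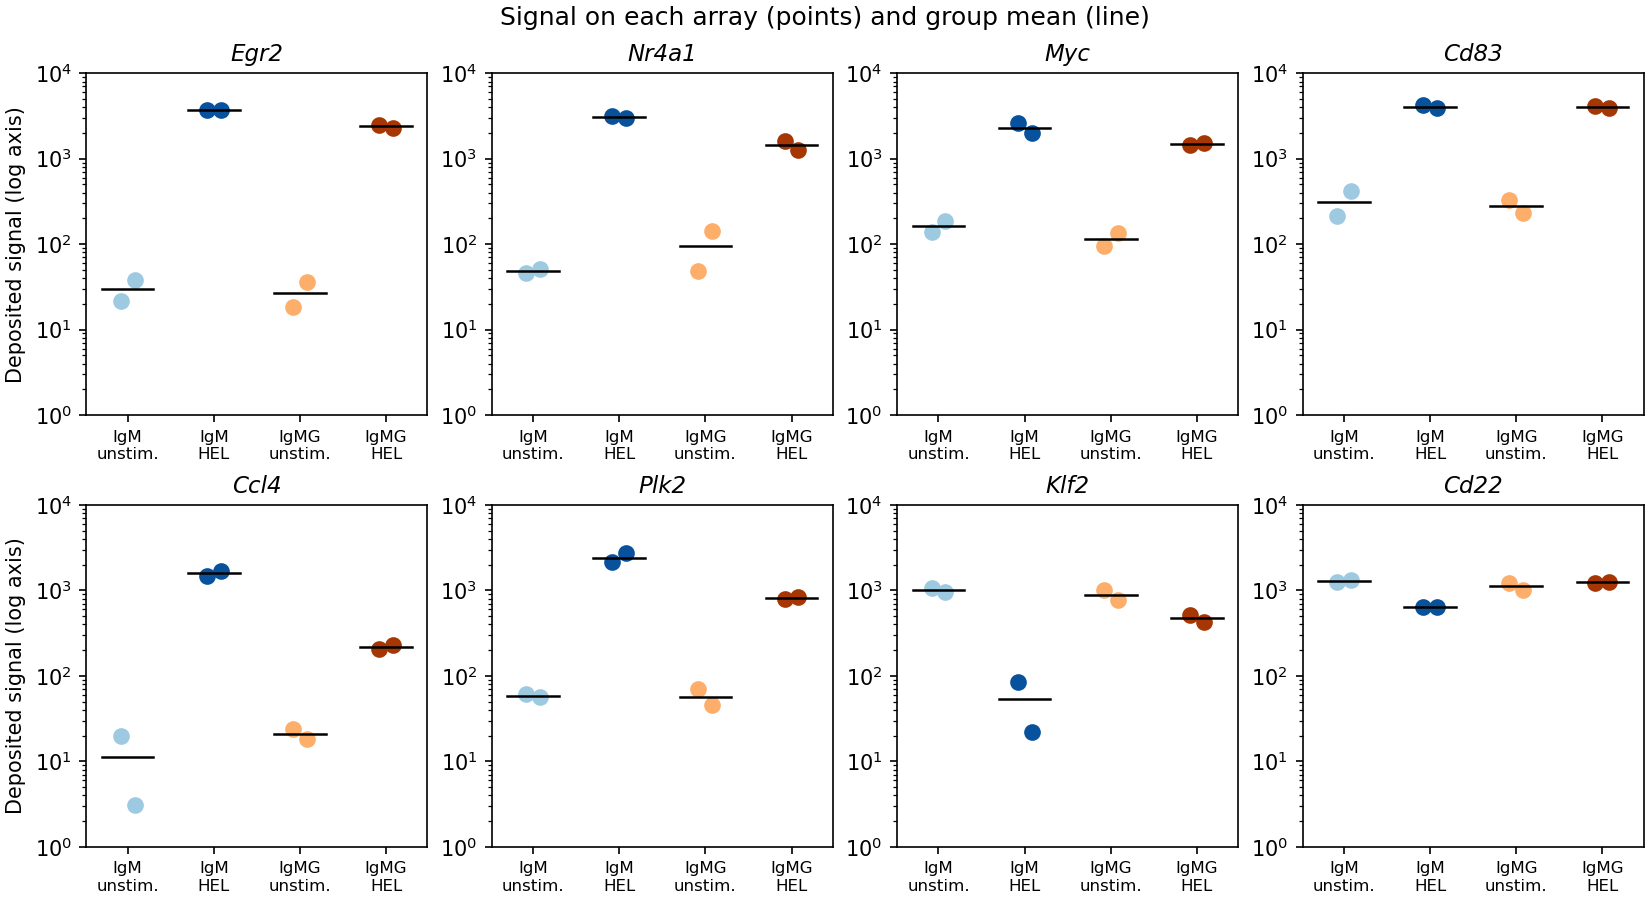
Deposited signal on a log axis for Egr2, Nr4a1, Myc, Cd83, Ccl4, Plk2, Klf2 and Cd22 in the 4 groups; points are arrays and lines are group means of 2 arrays. Cd83 reached a mean of 4054 in IgM and 4002 in IgMG cells with HEL, while Ccl4 reached 1588 and 217. Another Cd83 probe set, not drawn, rose less in IgMG cells. Its IgMG over IgM ratio of signal increases was 0.596 in the first and 0.0505 in the second replicates.

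The second comparison asked the same of IgMG B cells. Egr2 rose from 27.1 ± 12.7 to 2396 ± 153 (SD, n = 2 each), a log2 change of 5.84 ± 0.24 (SE), followed by Egr1 (4.46 ± 0.28), Bhlhe40 (4.07 ± 0.27), Nab2 (3.97 ± 0.20), Nr4a1 (3.84 ± 0.35), Gfi1 (3.82 ± 0.36), the activation marker Cd83 (3.78 ± 0.28), Myc (3.54 ± 0.22), Plk2 (3.52 ± 0.21) and the cyclic AMP response gene Crem (3.22 ± 0.26). The falls were smaller: Smpd2 (-2.12 ± 0.37), Bmyc (-1.97 ± 0.24), Scd2 (-1.93 ± 0.25), Rabgap1l (-1.81 ± 0.29), Il10ra (-1.81 ± 0.33) and the lipid receptor S1pr4 (-1.75 ± 0.27). By limma, 231 probe sets rose and 171 fell at an adjusted p under 0.05, 156 and 86 of them at least 2-fold. With each array centred on its median the split was 233 and 97.

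Of 15 immediate-early transcription factors 9 rose in IgMG cells (10 adjusted over the list alone), of 28 ribosome biogenesis genes 12 rose (19 adjusted over the list alone) and of 19 heat shock and chaperone genes 7 rose (9 adjusted over the list alone). Gnl3 rose by 2.38 ± 0.21, Tsr1 by 1.73 ± 0.19, Hsph1 by 1.63 ± 0.22 and Dnaja1 by 1.37 ± 0.19. Of 8 MAPK feedback genes 3 rose (6 rose and 1 fell adjusted over the list alone), among them Dusp2 at 2.67 ± 0.22 and Gem at 2.35 ± 0.21. Dusp6 had a log2 change of -0.47 ± 0.18 that missed the threshold, with an adjusted p = 0.159 in limma. Of 22 interferon-stimulated genes 5 fell (10 fell and 1 rose adjusted over the list alone). Camera in limma gave adjusted p-values of 1.02e-14, 6.48e-13, 6.53e-09, 4.48e-04 and 0.00174 for these 5 lists, but with an estimated correlation the adjusted p = 0.139 for each.

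Of 17 plasma cell and unfolded protein response genes 3 rose in IgMG cells, with Irf4 at 2.73 ± 0.17, Hspa5 at 1.44 ± 0.21 and Ddit3 (adjusted p = 0.0147 in limma). Nfatc1, of the calcium and NFAT list, rose by 2.65 ± 0.18 in IgMG and 2.99 ± 0.18 in IgM cells. Plaur rose by 1.36 ± 0.28, Cd5 by 1.39 ± 0.29 and Shmt1 by 1.66 ± 0.24, and Cd79b had a log2 change of -0.63 ± 0.14. Of 19 NF-kB genes 3 rose and 1 fell, and the list had an adjusted p = 0.0665 in limma's camera. Nfkbiz rose by 1.75 ± 0.30 and Tnf by 1.42 ± 0.23, while Relb (0.71 ± 0.22, adjusted p = 0.0963), Nfkbia (0.24 ± 0.16, adjusted p = 0.432), Cd86 (1.24 ± 0.41, adjusted p = 0.117) and Cd22 (0.14 ± 0.15, adjusted p = 0.647) missed the threshold in limma.

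Camera placed 9 of 30 lists past the threshold in IgMG cells, 8 higher and 1 lower, and fry placed 10. With an estimated correlation 0 lists passed, with the lowest adjusted p = 0.139. Markers of NK and myeloid cells did not pass with all arrays (adjusted p = 0.337 and 0.846 in limma's camera). Without the second unstimulated IgMG array, where both were highest, they passed as higher with HEL, with medians of 0.59 and 0.90 and adjusted p-values of 0.0431 and 1.96e-04. The 402 calls became 71 without the first and 58 without the second HEL-stimulated IgMG array, and 265 without the second unstimulated IgM array. They became 256 with no filter on dim probe sets, 231 with no trend, 163 with only the 4 arrays of the comparison and 163 with the 5'/3' covariate.

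Most calls in IgMG cells were shared with IgM cells. Of the probe sets that rose, 180 did so in both, against 15.5 for independent lists, and of those that fell 114 did so in both, against 12.4. No probe set was called in opposite directions. The responses, measured on separate arrays, correlated with r = 0.62 and rho = 0.50 across the tested probe sets, which are not independent replicates.

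**Figure D2:**
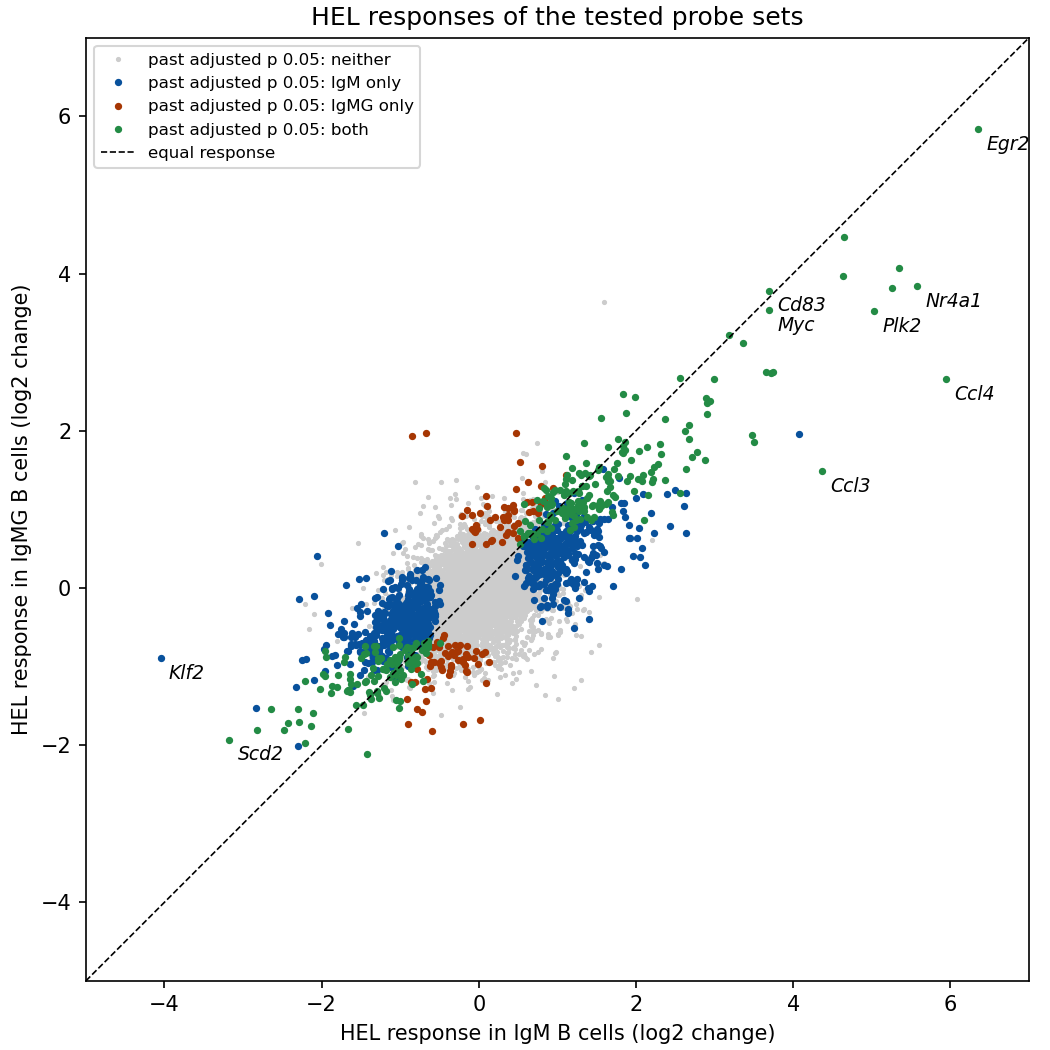
Log2 change with HEL in IgM cells (horizontal axis) against IgMG cells (vertical axis) for the 7453 tested probe sets, coloured by whether each response passed an adjusted p of 0.05. Ccl4 lies at 5.94 and 2.66 and Klf2 at -4.05 and -0.89, away from the dashed line of equal response.

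The third comparison, named in the design, asked whether the responses to HEL differed between the receptors. In this test 0 of 7453 probe sets passed an adjusted p of 0.05 in limma, while 750 had an unadjusted p under 0.05, against 372.65 by chance. Ccl4 had the smallest p: its log2 rise was smaller in IgMG, with a difference of -3.28 ± 0.40 and an adjusted p = 0.102. Its signal with HEL was 1588 ± 164 in IgM and 217 ± 16.3 in IgMG cells (SD, n = 2 each). Klf2 stood at 53.1 ± 43.6 with HEL in IgM and 471 ± 63.1 in IgMG cells (SD, n = 2 each), a difference of responses of 3.16 ± 0.54, with an adjusted p = 0.414 in limma.

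Ccl3 differed by -2.87 ± 0.46 (adjusted p = 0.379 in limma). The next values all had an adjusted p = 0.414: Dusp6 (1.42 ± 0.25), the inhibitory coreceptor Cd22 (1.12 ± 0.21), Plk2 (-1.50 ± 0.29), Atf4 (-1.30 ± 0.26), Rgs19 (1.29 ± 0.27), the phosphate transporter Slc20a1 (-1.24 ± 0.26) and Nr4a1 (-1.73 ± 0.50). Cd22 had mean signals of 1284 and 643 in IgM cells without and with HEL, and of 1129 and 1239 in IgMG cells. Sema4b differed by 2.47 ± 0.31 (adjusted p = 0.102), but both of its other probe sets had the opposite sign. Egr2 (-0.52 ± 0.35), Egr1 (-0.19 ± 0.40), Myc (-0.15 ± 0.31) and Cd86 (-1.25 ± 0.58) had adjusted p-values of 0.603, 0.895, 0.892 and 0.485 in limma.

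In 4 lists fixed before the data were examined, the members' responses differed by camera. The NF-kB list (median difference -0.50) and the quiescence list (0.50) had an adjusted p = 0.0264 in limma, and the translation list (-0.37) and the interferon-stimulated list (0.51) an adjusted p = 0.0495. No member passed over all genes, and adjusted over the list alone 1 quiescence and 1 interferon-stimulated gene did. With an estimated correlation the adjusted p = 0.470 for each of them, by fry the adjusted p = 0.218, and 0 lists passed by either. Without the second HEL-stimulated IgM array, which has the highest 5'/3' ratio, 0 lists passed, and the medians were -0.44 for NF-kB, 0.30 for quiescence, -0.21 for translation and 0.29 for interferon-stimulated genes. Without the second unstimulated IgMG array, translation (median -0.35, adjusted p = 0.0580 in limma) and interferon-stimulated genes (0.58, 0.0749) lost their calls with medians about as large as before. The NF-kB list (-0.31, 0.0317) and the quiescence list (0.33, 0.0248) kept theirs with smaller medians. Ribosome biogenesis (0.0248) and the markers of myeloid cells (median 0.85, adjusted p = 6.98e-04) and erythroid cells (median 1.04, adjusted p = 0.0132) then passed as well.

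On simulated data with 200 changed probe sets, this test recovered 0% of differences of 1 and 79% of differences of 2 on the log2 scale. In that setting differences of up to 2-fold were not detected. Recovery with another number of changed probe sets was not simulated. Without the first unstimulated IgMG array 13 probe sets passed, without the second 6, and without the first unstimulated or the first HEL-stimulated IgM array 1 each.

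The size of the whole response was compared on probe sets chosen by the mean of both responses, a choice that favours neither receptor. The 684 probe sets that rose had a mean log2 change of 1.09 in IgM and 0.84 in IgMG cells, a ratio of 0.765, and 469 of them (68.6%) changed less in IgMG. The 821 that fell had -0.91 and -0.68, a ratio of 0.745, and 571 (69.5%) changed less in IgMG. Both stimulated IgMG arrays lay below both stimulated IgM arrays, at 0.81 and 0.86 against 1.04 and 1.14 for the probe sets that rose. The Gapdh 5'/3' signal ratios of the stimulated IgMG arrays also lay below those of the stimulated IgM arrays, at 0.221 and 0.140 against 0.328 and 0.755. Between the stimulated IgMG arrays the order was the reverse: the array with the smaller response had the higher ratio. The difference in response size narrowly missed the threshold by fry in limma, with an adjusted p = 0.0501 for each set. Chosen on the IgM response alone the ratios were 0.619 and 0.523, and on the IgMG response alone 0.954 and 1.07. Without the second unstimulated IgMG array they were 0.894 and 0.851, and they passed the threshold without the first HEL-stimulated IgM array (0.666 and 0.574) or the second unstimulated IgM array (0.711 and 0.687).

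**Figure D3:**
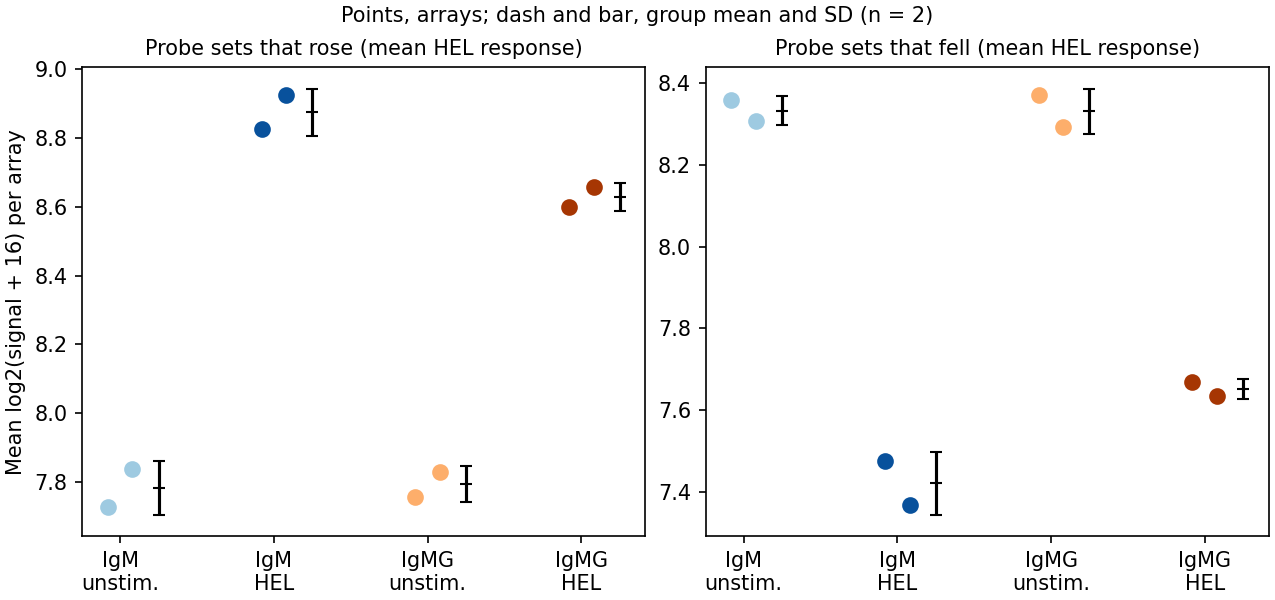
Mean log2(signal + 16) on each array over the 684 probe sets that rose (left) and the 821 that fell (right), with group mean and SD of 2 arrays. Probe sets that rose averaged 8.87 ± 0.07 in IgM and 8.63 ± 0.04 in IgMG cells with HEL.

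The fourth comparison asked whether the cells differed before antigen. The tyrosine phosphatase gene Ptpn22 had a mean signal of 187 ± 12.1 in IgM and 586 ± 219 in IgMG cells (SD, n = 2 each), a log2 difference of 1.52 ± 0.25 (SE). The protease Ctse (1.91 ± 0.36), the lipid carrier Apoe (2.02 ± 0.44), Socs5 (1.39 ± 0.29) and the Notch regulator Dtx1 (1.22 ± 0.27) were also higher in IgMG, and Sema4b was lower (-1.28 ± 0.22), though Ctse and Sema4b each had a probe set of opposite sign. Without the second unstimulated IgMG array, which has the highest NK and myeloid markers, the differences were 1.28 for Ctse, 1.35 for Apoe and 1.14 for Ptpn22 and did not pass. Without the first they were 2.54, 2.68 and 1.90 and passed (adjusted p = 0.00374, 0.0194 and 0.00686 in limma). With all 8 arrays none passed: limma gave these genes an adjusted p = 0.965, 0 of 7453 probe sets passed, and 344 had an unadjusted p under 0.05, fewer than the 372.65 expected by chance. The cyclin gene Ccnd2 had a difference of -1.53 ± 0.40 and the same adjusted p = 0.965, and Cd22 of -0.19 ± 0.15.

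Markers of NK cells (median difference 1.14 over 10 genes) and of myeloid cells (0.65 over 25 genes) were higher in unstimulated IgMG cells by camera in limma, with adjusted p = 4.90e-07 and adjusted p = 1.46e-04. With an estimated correlation the adjusted p = 0.557 and the adjusted p = 0.611. Both lists were highest on the second unstimulated IgMG array, and without it the medians were 0.23 and -0.06, with adjusted p = 0.0993 and adjusted p = 0.633. Markers of marginal zone B cells were also higher in unstimulated IgMG cells, with an adjusted p = 0.00628 by camera with all arrays. Their median difference was 0.50 without the second unstimulated IgMG array. With an estimated correlation their adjusted p = 0.557. Ribosome biogenesis (median -0.18, adjusted p = 0.00291 in limma) and interferon-stimulated genes (-0.21, 0.00601) were lower and cytokines and chemokines (0.17, 0.0348) higher in unstimulated IgMG cells, and with an estimated correlation the adjusted p = 0.557 for each. Without the second unstimulated IgMG array these calls were lost (0.160, 0.0993 and 0.222) while the medians stayed at -0.14, -0.27 and 0.20. Then cell cycle genes (0.00555), erythroid markers (0.00555, median -0.63) and immediate-early factors (0.0420) passed as lower. The count of 0 probe sets became 32 without the first and 8 without the second unstimulated IgMG array, and 17 without both arrays that stand apart.

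**Figure D4:**
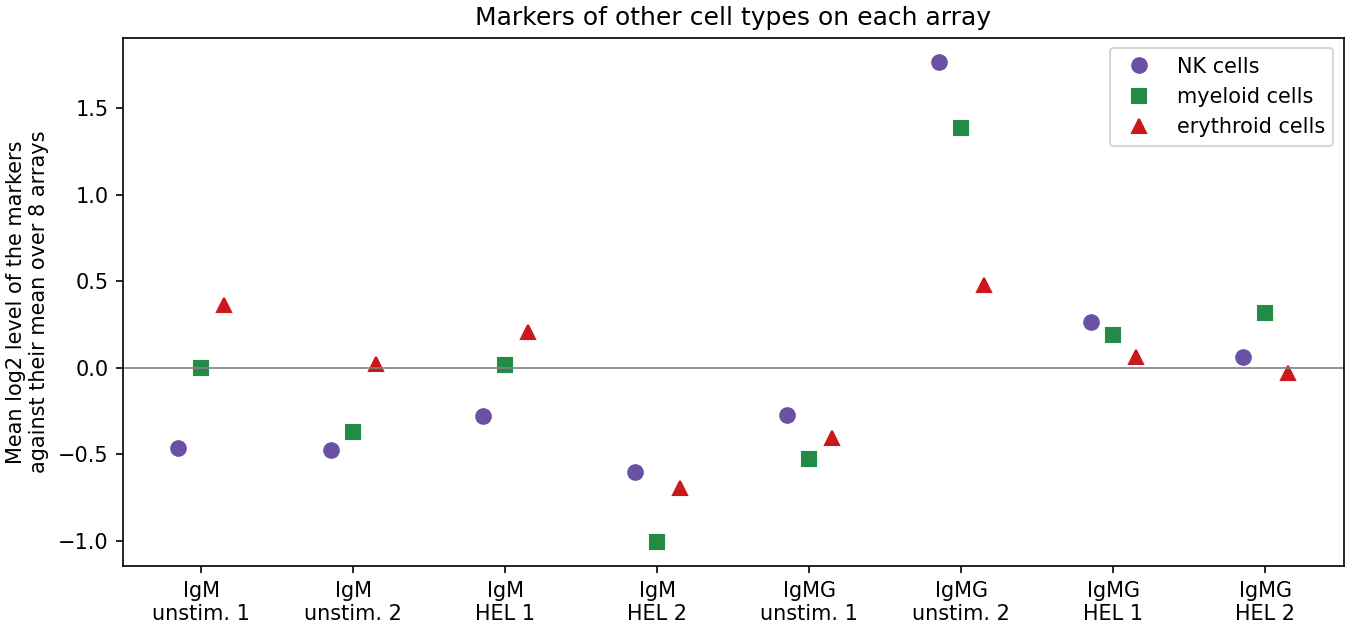
Mean log2 level of NK, myeloid and erythroid marker genes on each array against their mean over 8 arrays. The second unstimulated IgMG array has the highest NK (1.77) and myeloid (1.39) levels, and the second HEL-stimulated IgM array the lowest myeloid level (-1.01).

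The fifth comparison asked whether the cells differed after antigen. Ccl4 was the only probe set past the threshold in limma, lower in IgMG by 6.88-fold (log2 difference -2.78 ± 0.28, adjusted p = 0.0358), and 1037 had an unadjusted p under 0.05. Klf2 (2.97 ± 0.38), Plk2 (-1.54 ± 0.21), Irs2 (-1.72 ± 0.24) and the heparan sulfate enzyme Hs3st1 had an adjusted p = 0.0770. Hs3st1 read 4.7 and 8.6 in IgM and 89.0 and 68.5 in IgMG cells, and its log2 difference ranged from 1.01 to 3.42 with the offset, so it is only a rough value. Ccl3 (-2.06 ± 0.32), Txnip (1.04 ± 0.16) and Cd22 (0.93 ± 0.15) had an adjusted p = 0.115, and Smc4 (1.17 ± 0.19) and Rnf145 (1.23 ± 0.21) an adjusted p = 0.129. A second Txnip probe set had the opposite sign. Egr2 (-0.62 ± 0.24), Egr1 (-0.25 ± 0.28), Myc (-0.60 ± 0.22), Nr4a1 (-1.09 ± 0.35) and Cd86 (-1.09 ± 0.41) had adjusted p-values of 0.316, 0.723, 0.288, 0.253 and 0.294 in limma.

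The stimulated IgMG arrays had lower Gapdh 5'/3' ratios than the stimulated IgM arrays, 0.221 and 0.140 against 0.328 and 0.755. By camera in limma, 8 lists differed between stimulated cells. Ribosome biogenesis (adjusted p = 1.87e-06), immediate-early factors (0.00719), cholesterol synthesis (0.00719), the NF-kB list (0.00840) and translation (0.0155) were lower in IgMG. The quiescence list (0.0192), NK markers (0.0367) and myeloid markers (0.00204) were higher. With an estimated correlation 0 lists passed and the lowest adjusted p = 0.528, and fry gave a lowest adjusted p = 0.135. Without the second HEL-stimulated IgM array 3 lists passed: ribosome biogenesis, cholesterol synthesis and immediate-early factors. The medians of the NK and myeloid markers went from 0.83 and 0.70 to 0.62 and 0.20, those of the quiescence and translation lists from 0.36 and -0.25 to 0.12 and -0.19, and that of the NF-kB list from -0.14 to -0.21. Ccl4 lost its call when any of the 4 HEL-stimulated arrays was left out (adjusted p = 0.0736, 0.249, 0.472 and 0.242 in limma), and with an offset of 1, no filter, no trend or the 5'/3' covariate, while its log2 difference stayed between -2.89 and -2.52. The count was 0 without the second HEL-stimulated IgM array or without the first or second HEL-stimulated IgMG array, and 5 without the first or without the second unstimulated IgMG array.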

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

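The tests of RNA quality, array scaling and arrays that stand apart, and the count of markers on the second unstimulated IgMG array, were chosen only after the result was seen, as was the extension of the matched-list test from the 4 picked lists to all 30. With the values known, the bound for judging RNA quality, scaling and arrays that stand apart was reset from a fixed ratio to an interval, and the reading of the dilution test was changed from excluded to open.

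The responding probe sets drew attention because their response to HEL differed between the receptors. By fry's test for changes in either direction, the adjusted p = 0.00409 for those that rose and the adjusted p = 0.00409 for those that fell, although the test for a shift on balance one way stopped at an adjusted p = 0.0501. The combined rise minus fall was smaller in IgMG, with a ratio of 0.756 and a 95% interval of 0.577 to 0.971 from the spread between arrays, and a factor per array leaves this ratio alone, which argues against scaling. Uniform dilution by cells that did not respond predicts that the ratio of signal increases is alike for all induced probe sets. The ratios from the first and second replicates correlated across 208 probe sets with r = 0.332 (0.205 to 0.448) and rho = 0.419 (permutation p = 1.00e-04 for r). This r is above the 0.2 that dilution was said beforehand to stay under. The interval, however, reaches below the 0.3 set to exclude dilution and treats probe sets as independent. Arrays were also matched by replicate number, which does not pair them, and only this matching was computed. The values therefore lean against dilution and leave it open. RNA quality and the arrays that stand apart remain open too: the ratio was 0.809 (0.522 to 1.21) with the 5'/3' covariate and 0.837 (0.545 to 1.25) without both arrays. A smaller response in IgMG cells and no difference are therefore both possible. The receptor's exchanged part remains an untested explanation, as does the larger number of mice pooled on the IgMG arrays.

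The other flags are 4 gene lists whose responses differed between the receptors in limma's camera: NF-kB (adjusted p = 0.0264), quiescence (adjusted p = 0.0264), translation (adjusted p = 0.0495) and interferon-stimulated genes (adjusted p = 0.0495). All were lost in camera with an estimated correlation (adjusted p = 0.470 each). That setting passed 0 lists in every comparison, both HEL responses included, so a call lost there decides nothing about a list. A candidate explanation is the generally smaller response, so each list's median difference was placed among 10000 random lists matched on the mean HEL response. They lay at percentiles 0.70, 97.7, 1.82 and 99.3, all outside the central 95%, the bound set before the test. That bound was too generous for lists picked out of 30 for their difference: over all 30 lists 9 lay outside against 1.5 by chance, and 0 passed after adjustment (lowest adjusted p = 0.112). The most extreme were NK cell markers (percentile 0.24, median -0.50) and chemokine receptors (0.53, median -0.44). Without the second unstimulated IgMG array, where NK markers were highest, their median differences were 0.51 and -0.15. Whether the 4 flagged lists differ beyond the general response size cannot be told apart with these arrays.

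Other divisions of the 8 arrays into 4 and 4 were compared in limma for the mean responses. HEL against unstimulated gave 1386 calls in a fit of 2 groups. Of 35 splits 1, the real split itself, gave as many, with 0 calls in the highest other. Every other split mixes stimulated and unstimulated arrays, so a HEL response adds to the spread within its groups and holds calls down. The 0 calls of the other splits are therefore no measure of the number expected by chance. If stimulation changed nothing, however, each of the 35 splits would be equally likely to give the most calls. Only the real split gave calls, which met the bound set before the test and argues against chance for the mean HEL response. IgMG against IgM gave 0 calls in the fit of 2 groups, a count that all 35 of 35 splits reach by construction (highest other 1386, the stimulation split). That count therefore decides nothing about chance. In the fit of 4 groups the mean HEL response had 1505 calls, and the mean IgMG effect had 0, with 575 at an unadjusted p under 0.05.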

How the results depend on the processing

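The 5'/3' covariate, leaving out both arrays that stand apart, the crossed pairing and a single choice of probe sets were chosen after seeing the data; the fixed choice of probe sets was added once the ratios with probe sets chosen anew had been seen to move towards 1. Causes were not tested except where the construction (fewer arrays or probe sets, a stricter rule) gives them. Of the values of single genes that were checked, 2674 kept their direction and side of the threshold, 85 lost their call, 40 gained one and 14 changed sign, none of them called. Changes given only under Other observations, such as those of Inpp5d, Cxcr4 and Irf8, were not part of this check. Dim signals limit what can be seen: 31.4% to 34.6% of probe sets per array read 16 or less.

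Counts for IgM HEL, IgMG HEL, the difference, unstimulated and HEL-stimulated cells moved over 1.5 times as follows. IgM HEL: 575 at 2-fold, 316 by the rule without a test, 603 with the covariate. IgMG HEL: 256 without a filter, 231 without trend, 163 with only its arrays, 797 at adjusted p 0.10, 242 at 2-fold, 150 by the rule without a test, 163 with the covariate. Difference: 1 with offset 64, 4 without both arrays. Unstimulated: 17 without both arrays, 11 by the rule without a test. HEL-stimulated: 0 with offset 1, without a filter, without trend or with the covariate, 6 with offset 64, 2 centred on medians, 4 with only its arrays, 7 at adjusted p 0.10, 31 by the rule without a test. Mean HEL response: 396 at 2-fold. Mean IgMG effect: 1 with offset 64.

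Lists for the difference: 2 centred on medians, 2 without a filter, 2 with probe sets averaged, 0 by fry, 0 with the covariate, 1 without both arrays. Unstimulated: 3 with the brightest 40%, 0 by fry. HEL-stimulated: 0 by fry, 5 with the covariate, 4 without both arrays. With an estimated correlation 0 lists passed in each of the 5 comparisons.

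The response ratio (rose, fell) passed the threshold with offset 64 (0.761, 0.751), no filter (0.765, 0.730), no trend (0.763, 0.751), averaged probe sets (0.761, 0.758), a replicate block (0.761, 0.730), and, for those that fell, quantile normalization (0.712). Centred on medians it was 0.843 and 0.656. It was 0.619 and 0.523 when chosen on IgM, and reversed to 1.07 for those that fell when chosen on IgMG, choices that favour the receptor used. Without both arrays it was 0.935 and 0.879 with probe sets chosen anew and 0.836 and 0.838 with those chosen on all 8 arrays.

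Leaving out each array, where a lone array is assumed to vary like the other groups, gave 340 to 1285 calls for IgM HEL, 58 to 369 for IgMG HEL, 0 to 13 for the difference, 0 to 32 unstimulated, 0 to 5 HEL-stimulated, 837 to 1597 for the mean HEL response and 0 to 43 for the mean IgMG effect. Lists: 13 to 14, 7 to 11, 0 to 6, 2 to 6 and 3 to 8 in the order of the comparisons. Ratios: 0.666 to 0.894 (rose) and 0.574 to 0.874 (fell), and 0.728 to 0.805 and 0.702 to 0.792 with probe sets chosen once, where only leaving out the first HEL-stimulated IgM array passed the threshold (0.732 and 0.703).

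Signs changed for Ighm in IgM HEL (0.00 with quantile normalization, -0.00616 with the covariate) and unstimulated (0.00580 averaged, -0.27 to 0.24 leaving out arrays, highest without the first unstimulated IgMG array), Cd79a unstimulated (-0.0129 centred on medians, -0.0896 to 0.19 leaving out arrays, below 0 without the first unstimulated array of either receptor), Cd86 HEL-stimulated (0.13 with the covariate), and the differences of Egr1 (-0.58 to 0.20 leaving out arrays) and Myc (-0.38 to 0.0729), above 0 without the first unstimulated IgM, the first HEL-stimulated IgM and the second unstimulated IgMG array.

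Replicate differences correlated between groups at -0.16 to 0.02, so the numbers do not pair the arrays. With the replicate block IgM HEL had 869 calls, IgMG HEL 273 and HEL-stimulated 3, against 1041, 402 and 1. Of the counts only the HEL-stimulated one moved over 1.5 times. Crossed pairing of the unstimulated arrays gave 0 calls.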

Other observations

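The count of markers on the second unstimulated IgMG array was chosen only after the result was seen.

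Several lists moved both ways with HEL and passed no list test, while single members changed. Among inhibitory receptors and phosphatases 4 of 16 rose and 4 fell in IgM cells: Ptpn22 rose by 2.22 ± 0.25 and the lipid phosphatase Inpp5d by 1.22 ± 0.18, while Cd22 (-0.98 ± 0.15) and the Fc receptor Fcgr2b (-0.86 ± 0.16) fell. Among receptor-proximal signalling genes 4 of 21 fell, including Cd79b (-1.01 ± 0.14), the adaptor Blnk (-1.18 ± 0.18) and the kinase Syk (-0.91 ± 0.18), and Blk rose by 0.69 ± 0.14. In IgMG cells Ptpn22 rose by 1.38 ± 0.25 and Blk by 0.69 ± 0.14. The camera adjusted p of these lists in limma was 0.593 and 0.683 in IgM cells.

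Of 14 chemokine and guidance receptors, the retention receptor Cxcr4 rose by 1.72 ± 0.19 in IgM and 1.51 ± 0.19 in IgMG cells, and S1pr4 fell by 2.14 ± 0.27 in IgM cells. The germinal centre list rose by camera in both, with an adjusted p = 0.0206 in IgM and an adjusted p = 0.0359 in IgMG cells in limma, and with an estimated correlation an adjusted p = 0.143 and an adjusted p = 0.211. Irf8 rose by 0.88 ± 0.14 and 1.17 ± 0.14 and Mef2c by 1.17 ± 0.16 and 0.94 ± 0.16, while the B cell identity factor Pax5 had a log2 change of -1.02 ± 0.22 in IgM cells. Of 31 cell cycle genes 2 rose and 4 fell in IgM cells (median -0.13) and 1 rose and 1 fell in IgMG cells (median -0.10). The replication factor Pcna rose by 0.97 ± 0.18 in IgM and 1.25 ± 0.18 in IgMG cells, and the mitotic kinase Aurkb had a log2 change of -2.10 ± 0.42 in IgM cells. Of 21 oxidative phosphorylation genes 0 rose and 0 fell in either.

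On the second unstimulated IgMG array, 27 of 35 tested NK and myeloid markers had their highest signal of all 8 arrays, where 12.5% of a list is expected on any array. S100a8 read 5339 there and 371 on the other unstimulated IgMG array, Lyz2 1796 and 219, Gzma 1227 and 80.5, and the plasma cell gene Jchain 548 and 55.8. Of the 25 myeloid markers 7 were highest on the first HEL-stimulated IgMG array instead, among them Cd14 at 1005, C1qa at 550 and Csf1r at 540. Markers of other cell types were not confined to these arrays. S100a8 read between 215 and 2019 on the arrays of the other groups, and the erythroid marker Hba-a1 read 9595 to 16616 over the 8 arrays. A candidate explanation for the marker levels of the second unstimulated IgMG array is cells of other types in that sample. A sort for follicular B cells should have removed them. The count restates what drew attention to the array, so it is no test of this explanation, which stays open.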
